A study of Homo sapiens with 4 samples.

How the data were processed

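MCF7 cells had been treated with 10 µM VLX 50 or 0.1% DMSO for 6 h, and RNA from 1 sample per treatment was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The 4 deposited columns are the MAS5 and RMA summaries of the 2 arrays. The MAS5 columns hold signal intensity on a linear scale and the RMA columns hold log2 expression, as deposited by the authors, with MAS5 and RMA named per the submitters' processing notes. The software versions and the scaling settings are not given in the sources used here. Scale was checked from the values: the slope of log2 MAS5 intensity on RMA was 0.988 on the VLX 50 array over 3963 probe sets with high RMA values and no altered MAS5 value. With the altered MAS5 values restored by the rule given with the alternatives, log2 of each MAS5 column correlated most with the RMA column of the same label (r 0.891 against 0.882 for VLX 50, and 0.895 against 0.884 for DMSO, across probe sets).

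Probe sets were named from the platform annotation. Of 54675 probe sets, 62 were controls, 41091 had 1 gene, 1801 had several and were left unnamed, and 11721 had none listed. Of those with 1 gene, 41043 were found by Entrez id in the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. No genome build is named in the files, so no coordinates are given. Each of 19775 genes was represented by its probe set with the highest mean RMA value. The floor was the median of the mean RMA values over probe sets, 4.65, which left 13043 genes. A gene was counted as higher or lower if its log2 difference, VLX 50 minus DMSO, was at least 1 in that direction in both summaries. The MAS5 columns entered as deposited, including those that are whole minutes of a day. For each list the median RMA difference was set against 10000 random lists of the same size drawn within 10 bins of mean level, and a list stood apart when its percentile was under 2.5 or as far into the upper end. Lists needed 8 genes above the floor.

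The genes named are the 15 with the highest and the 15 with the lowest RMA difference among those counted (13 were counted as lower), up to 5 members per list with the largest absolute difference, and the controls. VEGFA, AK4, CA12, PPP1R3C, CDK1, SCNN1G, PABPC1L and MAP3K8 were named after their values were seen, as were the genes of the families in the other observations. The count rule, the floor, the lists, the naming rule and the first set of alternative settings were chosen before the data were examined. Restoring such MAS5 values, leaving their probe sets out and scaling to the spikes were chosen after. A MAS5 value was taken as altered if it had 8 or more digits and was a whole multiple of 1 minute in units of a day, and was restored as hours before and minutes after the decimal point.

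On simulated data made from the 13043 genes with 1 array per treatment, 92% of genes changed by 1.5 on the log2 scale were recovered. Of those changed by 2.5, 100% were recovered, and there were 0 false calls. The simulated noise was normal, with no spread between cultures and no altered MAS5 values. The 0 false calls therefore say nothing about errors among the genes counted here. On the deposited values, 3.5% of 200 random lists fell outside the bounds. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.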

Results

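Gene expression was measured in MCF7, an oestrogen receptor-positive human breast cancer cell line, after 6 h with 10 µM VLX 50 or with 0.1% DMSO, the solvent. VLX 50 is a small molecule that the series describes as a hit of a compound screen. Biotin-labelled RNA made from 2 µg of total RNA was hybridised to 1 Affymetrix GeneChip array per treatment, and each array was summarised by MAS5 and by RMA, which gave 4 columns over 54675 probe sets. The 2 arrays have no replicates, and the MAS5 and RMA columns are 2 summaries of the same arrays. No test between treatments was therefore possible, and every difference below describes these 2 arrays. The number of arrays limits the precision. The nearest measure of error was the spread between probe sets of one gene, whose pooled SD was 0.25 on the log2 scale. The median RMA value was 4.66 on the VLX 50 array and 4.64 on the DMSO array, and the median MAS5 intensity was 74.7 and 69.6.

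The comparison of VLX 50 with DMSO asked which transcripts differed after 6 h with the compound. Genes known to be induced by hypoxia-inducible factor (HIF) were higher on the VLX 50 array, and genes of the G2 phase and mitosis were lower. PDK1, the kinase that inhibits pyruvate dehydrogenase, was 5.58-fold higher in RMA (log2 difference 2.48) and 2.64 higher in MAS5 by its brightest probe set, while its other probe set above the floor differed by 0.82. Of 13043 genes above the floor, 26 were at least 2-fold higher and 13 at least 2-fold lower on the VLX 50 array in both summaries. Over the same genes the RMA difference had a median of −0.02 and an SD of 0.27. The labelled spike transcripts added for hybridisation were themselves brighter on the VLX 50 array, by a median of 0.39 in RMA and 0.33 in MAS5. With both summaries scaled to these spikes, 9 genes were at least 2-fold higher and 153 lower, so the share of higher calls was 5.56% in place of 66.7%. All differences given here are relative to the deposited scaling, and a scaling to the median of the hybridisation spikes would lower each RMA difference by 0.39. Below, scaled to the spikes means this shift. It is a simplification, because these spikes ranged from −0.0066 to 0.66. The poly-A spikes, added before labelling, had a larger median of 0.78, and no scaling to them was made.

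Among 32 HIF target genes above the floor, 30 were higher and 2 lower on the VLX 50 array, with a median RMA difference of 1.03, or 2.05-fold. This median lay at percentile 100 among 10000 random lists of the same size and level, and 13 of the 32 genes were at least 2-fold higher in both summaries. They made up 13 of the 26 genes counted as higher. The size of the list's median depended on the processing, with percentile 100 throughout. It was 0.80 with the median over each gene's probe sets, 0.95 without _s_at and _x_at probe sets and 0.65 when scaled to the spikes. ANKRD37 was 2.16 higher, ADM, which encodes the vasodilator adrenomedullin, 1.82 higher, and BNIP3L and BNIP3, which act in mitophagy, 3.49-fold and 2.83-fold higher. PFKFB4, which makes a regulator of glycolysis, was 1.78 higher in RMA, although its other probe set differed by 0.18. EGLN1, an oxygen-sensing prolyl hydroxylase of HIF, and P4HA1, a collagen prolyl hydroxylase, were both 1.38 higher. DDIT4, an inhibitor of mTORC1 signalling, was 1.39 higher and NDRG1 1.36 higher. In RMA alone 17 list members were at least 2-fold higher, among them VEGFA, which encodes a growth factor of blood vessels, at 1.21, and AK4 at 1.10, whose MAS5 differences were 0.95 and 0.90. The remaining 2, PFKFB3 and KDM3A, were 1.90 and 1.24 higher in RMA but −2.50 and −3.32 in MAS5. The MAS5 value of PFKFB3 on the VLX 50 array is one of those with 8 or more digits described with the MAS5 columns, and that of KDM3A has fewer digits and is not counted among them. CA12 and PPP1R3C were the 2 members below 0, at −0.20 and −0.38.

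**Figure D1:**
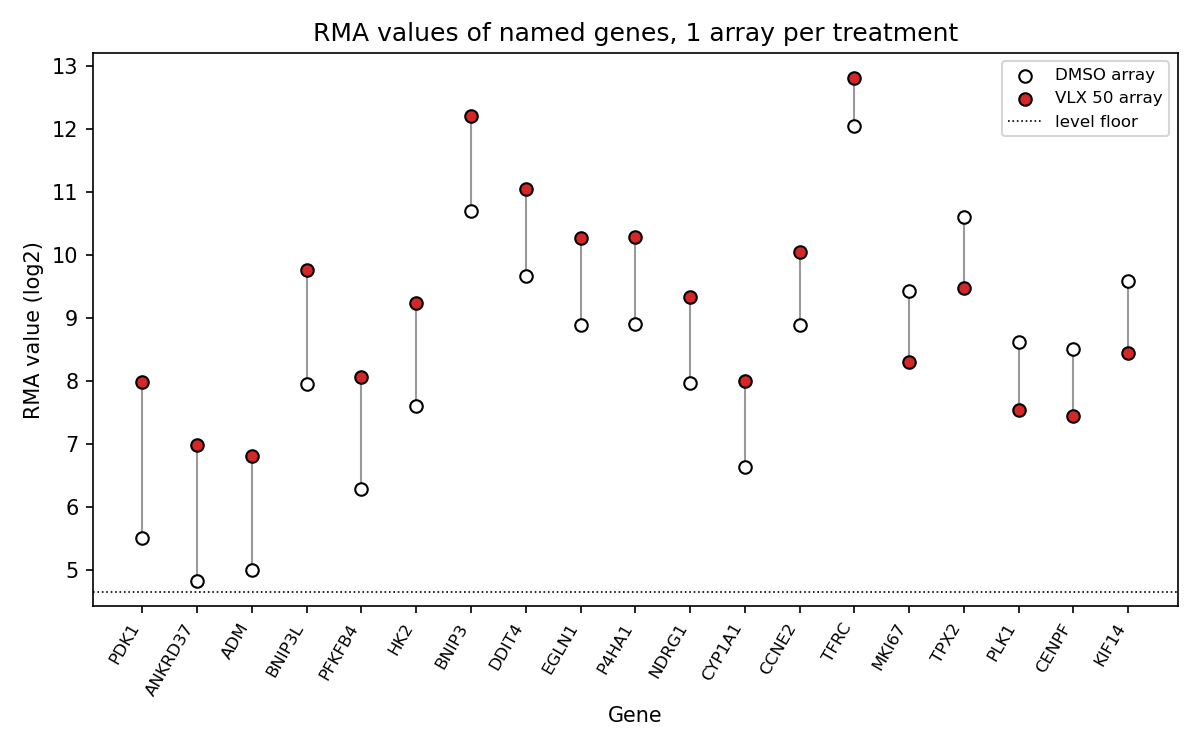
RMA value (log2, y axis) of genes named in the text (x axis) on the DMSO array (open points) and the VLX 50 array (red points), 1 array per treatment, with the floor of 4.65 as a dotted line. PDK1 lies at 5.51 and 7.99, and MKI67 at 9.43 and 8.30.

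The 19 glycolysis genes above the floor had a median RMA difference of 0.25, or 1.19-fold, at percentile 99.99, but −0.13 when scaled to the spikes. Of these, 17 were above 0 and 2 below. HK2, which phosphorylates glucose, was 1.64 higher and was the 1 list member counted in both summaries, although another of its probe sets did not differ (−0.0023). PGM1 was 1.21 higher in RMA and 0.79 in MAS5. SLC2A1, a glucose transporter, differed by 0.70, ENO2 by 0.68 and PGK1 by 0.58. The list shares 1 gene, SLC2A1, with the HIF list fixed here, and without it the median was 0.24 at percentile 99.98. This takes out that overlap alone, and whether other glycolysis genes are HIF targets was not tested.

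The list of aryl hydrocarbon receptor targets also holds AHR, the gene of the receptor. It had 8 genes above the floor, the fewest that allow a percentile, so without AHR it would have none. Its median was 0.19 at percentile 98.45, and −0.20 when scaled to the spikes. In MAS5 the median was 0.36 as deposited and 0.46 restored. CYP1A1, the most strongly inducible of these by aromatic ligands, was 1.36 higher in RMA and 1.57 in MAS5, and was the 1 member counted. CYP1B1 differed by 0.67, with probe sets from 0.02 to 0.67, and TIPARP by 0.47, while ALDH3A1 differed by −0.19 in RMA and 0.61 in MAS5, and AHR, the receptor itself, by 0.22 and −0.45. The list had 5 genes above 0 and 3 below.

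Of 31 genes of G2 and mitosis, 30 were lower on the VLX 50 array, with a median of −0.60, or 1.51-fold, at percentile 0. The 4 counted as at least 2-fold lower in both summaries were MKI67, the proliferation marker Ki-67, at −1.13, TPX2, a spindle assembly factor, at −1.11, PLK1, a mitotic kinase, at −1.08, and CENPF, a kinetochore protein, at −1.06. ASPM was at −1.07 in RMA and −0.82 in MAS5. CDK1 was the 1 member above 0, at 0.18. Genes of G1/S and DNA replication did not stand apart, with a median of 0.04 over 31 genes at percentile 93.2, but did at 0.13 (98.2) in MAS5 and at 0.10 (97.7) without _s_at and _x_at probe sets. In that list CCNE2, which encodes cyclin E2, was 1.16 higher and CDC25A was at −0.66. The 12 tubulin genes had a median of −0.16 at percentile 1.07, with 4 above 0 and 8 below. TUBB3 differed by −0.46 and TUBB4B by −0.34, and TUBE1 by 0.59. This position was lost in the MAS5 columns, where the median of −0.15 lay at percentile 5.05, and without a floor, where −0.11 lay at 4.95.

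**Figure D2:**
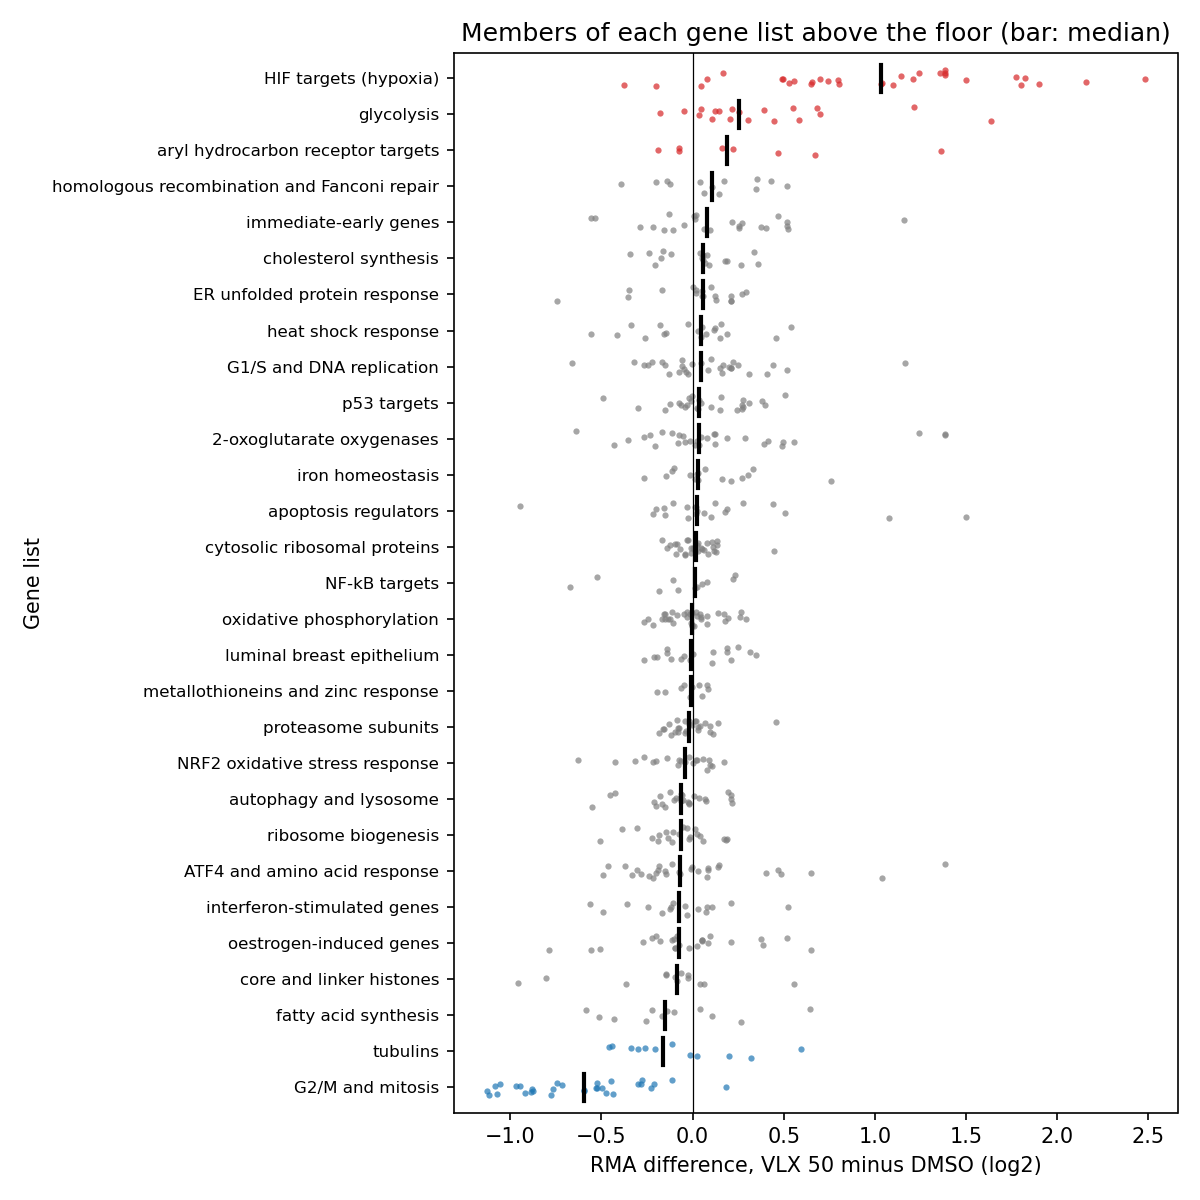
RMA difference (log2, VLX 50 minus DMSO, x axis) of each member above the floor (points) and the median (bars) of the 29 gene lists with a percentile, with lists standing apart in red where higher and blue where lower, relative to the deposited scaling (scaled to the spikes, glycolysis is at −0.13 and aryl hydrocarbon receptor targets at −0.20). The HIF targets have a median of 1.03 and the G2 and mitosis genes one of −0.60.

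Of the 26 genes counted as higher, 9 belonged to no list. POFUT4 was 1.73 higher, CIART, a repressor in the circadian clock, 1.43 higher, and BMP7 1.27 higher, although the probe sets of BMP7 ranged from −0.39 to 1.27. FOS, an immediate-early transcription factor of another list, was 1.16 higher. Of the 13 counted as lower, 9 belonged to no list. HINT3 was at −1.35, with another probe set at −0.19, CCAR1, a coactivator of cell cycle and apoptosis, at −1.32, KIF14, a mitotic kinesin, at −1.15, ARID1A, a subunit of the SWI/SNF chromatin remodelling complex, at −1.13 and AKAP13 at −1.02. Further probe sets of several of these went the other way, reaching 0.37 for CCAR1, 0.39 for ING3 (−1.07), 0.15 for ZBTB38 (−1.09) and 0.11 for TMEM260 (−1.03), and 0.28 for MBP, which was 2.00-fold lower. Among genes counted as lower outside the G2 and mitosis list with at least 2 probe sets above the floor, all probe sets were lower in 4 of 9. All probe sets were higher in 90.0% (18 of 20) of such HIF targets, and lower in 93.75% (15 of 16) of such genes of the G2 and mitosis list. Over all genes with at least 2 probe sets above the floor, all went the same way in 49.1%. That last share counts either direction, whereas the others count 1.

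In total, 33 lists were fixed, 29 had at least 8 genes above the floor, and 5 stood apart, where random draws of genes give 1.45. Such draws treat genes as independent. How many lists would stand apart between 2 cultures of the same treatment is unknown with 1 array each. The other 24 had medians from −0.15 to 0.11. Stress responses lay near 0, with medians of 0.05 for heat shock (percentile 84.6), −0.04 for the NRF2 response (35.4), 0.06 for the unfolded protein response (90.9), 0.03 for p53 targets (88.3) and −0.01 for metallothioneins and zinc response (58.5). List genes with no probe set assigned to them alone were not measured. For heat shock, where 19 of 24 genes were used, these include HSPA1A, HSPA1B, HSPA8 and AHSA1. For iron homeostasis they include FTH1, IREB2 and FXN. The ATF4 and amino acid list had a median of −0.07 (11.6), and −0.11 (3.13) without the 3 HIF targets it holds. Iron homeostasis had a median of 0.03 (80.6), with TFRC, the transferrin receptor, at 0.76 and its probe sets between −0.12 and 1.12. The 2-oxoglutarate oxygenases, the enzyme class to which EGLN1 belongs, had a median of 0.03 (89.9), and −0.01 (62.9) without 6 HIF targets. Oestrogen-induced genes had a median of −0.08 (15.4), with IGFBP4 at −0.79 and MYC at 0.52, and luminal breast epithelium −0.01 (58.4). Immediate-early genes reached 0.08 (97.3), but 0.21 (99.6) in MAS5 and −0.01 (64.0) in the median over probe sets, and homologous recombination and Fanconi repair 0.11 (95.6). Fatty acid synthesis lay at −0.15 (5.24), with FASN at −0.51, and cholesterol synthesis at 0.06 (91.7). Values were −0.08 (15.5) for histones, 0.01 (54.5) for NF-kB targets (−0.20 in MAS5), −0.07 (21.7) for interferon-stimulated genes and 0.02 (78.9) for apoptosis regulators, in which CASP8 was at 1.08 in RMA and 0.89 in MAS5, with RMA probe sets from 0.23 to 1.08. Housekeeping machinery gave −0.02 (34.5) for the proteasome, −0.0045 (54.4) for oxidative phosphorylation, 0.02 (74.1) for ribosomal proteins, −0.06 (25.4) for ribosome biogenesis and −0.06 (24.6) for autophagy and lysosome (0.11 in MAS5). Markers of other cell types had too few genes above the floor for a percentile: the median was 0.13 over 7 basal, 0.12 over 6 fibroblast, 0.01 over 6 leukocyte and 0.19 over 3 endothelial genes. In MAS5 the basal median was −0.37, the fibroblast median 0.51 and the endothelial median 1.24, and all 4 RMA medians lay below 0 when scaled to the spikes.

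The control transcripts differed between the arrays. Of 18 hybridisation spike probe sets 16 were higher on the VLX 50 array, from −0.0066 to 0.66. Of 24 probe sets of the poly-A spikes, which are added before labelling, 24 were higher, with a median of 0.78 and a range of 0.15 to 1.44. Their median was 0.99 at the 5′ end, 0.83 in the middle and 0.62 at the 3′ end. Of 17 human control probe sets 10 were higher on the VLX 50 array, with a median of 0.09 and a range of −0.69 to 0.91. Both ends of that range were ribosomal RNA probe sets. In one ribosomal RNA control the differences were 0.40 at the 3′ end, 0.38 in the middle and 0.91 at the 5′ end, so its 3′ minus 5′ difference was 0.07 on the VLX 50 array and 0.57 on the DMSO array. In the other they were 0.38, −0.69 and 0.42, and its 3′ minus 5′ difference was −3.47 and −3.43. Among messenger RNAs the 3′ minus 5′ difference was 0.30 on the VLX 50 array and 0.33 on the DMSO array for GAPDH, 0.66 and 0.65 for ACTB, and 3.51 and 3.56 for STAT1.

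Part of the MAS5 values did not match the RMA values of the same array. On the VLX 50 array 1149 values (2.10%) and on the DMSO array 1119 values (2.05%) had 8 or more digits, and all were whole minutes of a day within the rounding of their last digit. Read back as hours and minutes, they came close to the level given by RMA: for probe sets with an RMA value of at least 8, the median log2 distance went from −4.56 to 0.02 on the VLX 50 array and from −4.58 to 0.0024 on the DMSO array. The correlation across 13043 genes of the RMA with the MAS5 difference went from Pearson's r of 0.256 (Spearman's rho 0.524) as deposited to 0.403 (0.586) after restoring, where genes are not independent replicates. Restoring raised PFKFB3 to 2.08 in MAS5, and brought NDRG1 from 5.96 to 1.37 and KIF14 from −5.97 to −1.38. The count then was 27 higher and 13 lower, with PFKFB3 and SCNN1G gained and PABPC1L lost.

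**Figure D3:**
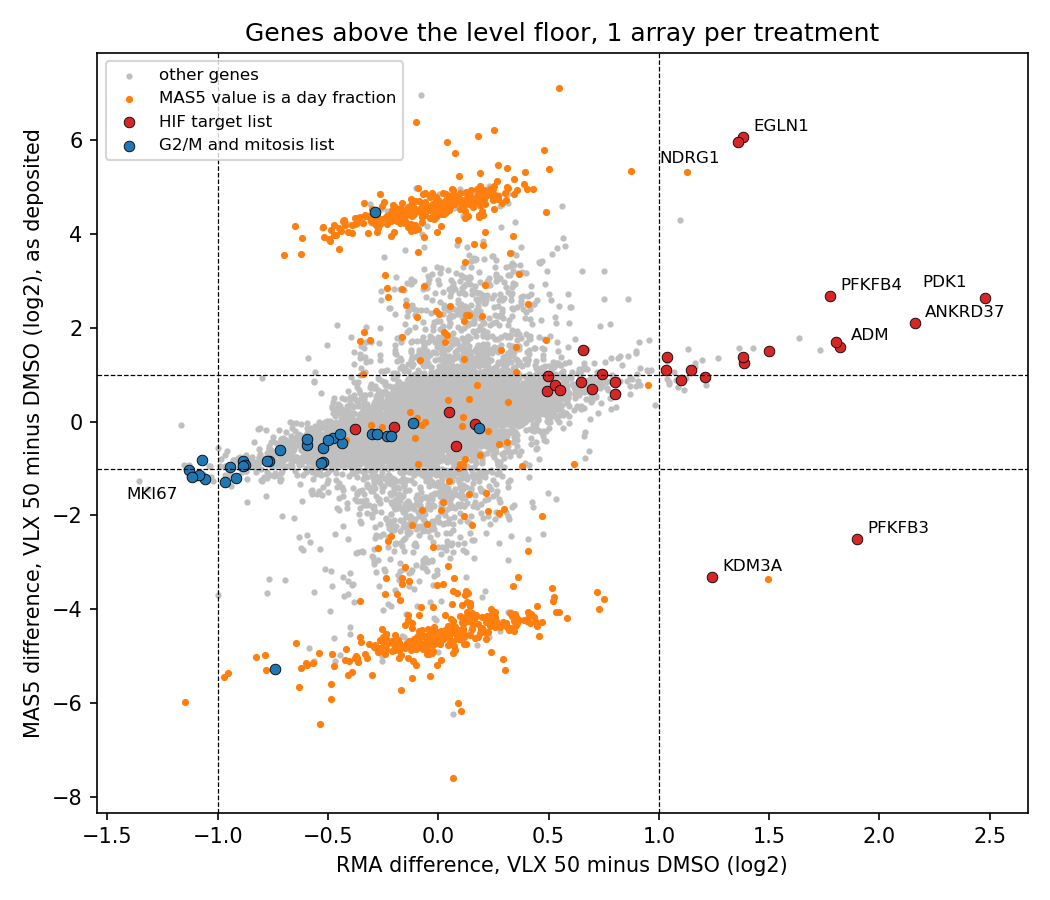
Each point is a gene above the floor, with its RMA difference (log2, VLX 50 minus DMSO) on the x axis and its MAS5 difference as deposited on the y axis, with red for HIF targets, blue for the G2 and mitosis list, orange for genes whose MAS5 value has 8 or more digits and is a whole minute of a day, grey for the rest, and dashed lines at 2-fold. EGLN1 and NDRG1 lie at 6.06 and 5.96 in MAS5 as deposited, against 1.38 and 1.36 in RMA.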

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

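The values from restored MAS5 columns and from scaling to the spikes were chosen after the result was seen. No replicate could be left out, and No paired analysis was possible because each treatment has 1 array. RMA alone gave 39 genes higher and 20 lower, MAS5 alone 1140 higher and 1014 lower (866 and 734 restored), and the median over probe sets 20 higher, 19 of them among the 26, and 6 lower, 4 of them among the 13. A 1.5-fold threshold gave 155 higher and 192 lower, a 3-fold threshold 6 and 0, and scaling to the hybridisation spikes 9 and 153, where a shift of all genes by construction moves the counts. The same shift put glycolysis at −0.13 and aryl hydrocarbon receptor targets at −0.20, with the percentiles unchanged. G1/S and DNA replication stood apart at 0.13 in MAS5, 0.13 restored and 0.10 without _s_at and _x_at probe sets. Immediate-early genes stood apart at 0.21 in MAS5, 0.15 restored, 0.16 without those probe sets and 0.12 with a loess trend removed, but not at 0.04 without a floor or −0.01 in the median over probe sets. Tubulins no longer did at −0.15 in MAS5, −0.15 restored and −0.11 without a floor. Among the lists with under 8 genes, basal epithelium was at −0.37, fibroblast at 0.51 and endothelium at 1.24 in MAS5, deposited and restored alike, and scaling to the spikes put basal epithelium at −0.26, fibroblast at −0.27, leukocyte at −0.38 and endothelium at −0.20. Apart from the spike shift, the cause was not tested. BMP7 (−0.39), MAP3K8 (−0.0034, a gene counted as higher) and TMEM260 (0.11) changed sign without _s_at and _x_at probe sets, and ING3 (0.11) in the median over probe sets, which follows from probe sets that differ. A loess trend removed left all 178 named genes within the spread between probe sets, and 123 were so in MAS5. With the floor at the 75th percentile 7 lists had too few genes for a percentile, among them the aryl hydrocarbon receptor targets. Without _s_at and _x_at probe sets 11 had, among them glycolysis, tubulins and the aryl hydrocarbon receptor targets, so 3 of the 5 lists that stood apart could not be checked there. Spike scaling aside, 0 of the 5 lists that stood apart and 13 of the 24 that did not changed the sign of their median under at least 1 setting, so the sign of a median near 0 carries no direction. Signal near the floor limits the lists of other cell types.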

Other observations

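Gene families below were chosen after values of some members were seen, so their percentiles are not independent evidence. SR splicing factors, CDC-like kinases and cyclins L, which act in pre-mRNA splicing, had a median RMA difference of 0.26 over 16 genes, 13 of them above 0, at percentile 100, and −0.13 when scaled to the spikes. SRSF5 was at 0.80, RSRP1 at 0.76, CCNL2 at 0.74 and CCNL1 at 0.59. The probe sets of RSRP1 ranged from −0.04 to 0.76 and those of CCNL2 from 0.08 to 0.74. Without the 3 members seen first, SRSF5, RSRP1 and CCNL2, the median was 0.22 over 13 genes at percentile 99.9. The KMT2, CHD and ARID chromatin regulators had a median of −0.28 over 22 genes, 17 of them below 0, at percentile 0.02, and −0.19 at 1.39 without ARID1A, CHD8, KMT2A and KMT2D, which had been seen first. Their probe sets differed, from −1.19 to −0.03 for KMT2A and from −0.91 to 0.31 for KMT2D.

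Kinesins had a median of −0.19 over 31 genes at percentile 0.05, and −0.16 over 25 genes at 1.22 without members seen first or in the G2 and mitosis list. Centromere proteins had −0.15 over 18 genes at 3.10, and −0.13 over 15 at 8.01 without members of that list. Genes named ZNF had −0.08 over 321 genes at 0.02, and −0.08 over 314 at 0.02 without those seen first or in the HIF list. The circadian clock list had 0.01 over 14 genes at 68.3, with CIART at 1.43 and PER2 at 0.52, and too few unseen members for a percentile.

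Of the tests that follow, the removal of a loess trend was chosen before its result was seen, and the others after. HIF targets were higher on the VLX 50 array. Were a trend with intensity the cause, the median would fall under 0.5 once the trend was removed, and it was 1.07. Over genes above the floor the RMA difference had a median of −0.02 and an SD of 0.27. These values limit a trend shared by most genes but not one confined to some levels. With the trend removed, 26 genes were counted as higher and 10 as lower, in place of 26 and 13. The random lists were already matched on level, so this removal adds no separate support. Single cross-hybridising probe sets would leave most genes with discordant probe sets, and in 90.0% (18 of 20) of list genes with at least 2 all were higher. That share counts direction and not size: PDK1 differed by 2.48 and 0.82, and PFKFB4 by 1.78 and 0.18. The rest of the 32 genes, among them ANKRD37, ADM, DDIT4, P4HA1 and NDRG1, had 1 probe set above the floor and could not be checked. A difference between the cultures other than the compound cannot be told apart from the compound with 1 array per treatment.

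Genes of G2 and mitosis were lower. Fewer cells in every phase of the cycle was taken to lower G1/S genes alike. The G1/S median lay 0.64 above that of G2 and mitosis, where its members had an SD of 0.32. This SD is the spread among genes and not the error of either median, and the comparison was set after both medians were seen. Because 2 µg of total RNA was labelled per treatment, fewer cells need not lower either list, so the comparison does not decide on this explanation. In 93.75% (15 of 16) of list genes with at least 2 probe sets above the floor all were lower, which argues against single cross-hybridising probe sets in those genes. The rest of the 31 genes, among them TPX2, PLK1 and CENPF, had 1 and could not be checked. A different share of cells in G2 and mitosis, lower transcription of these genes and a difference between the cultures stay open and were not tested.

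Some MAS5 values lay far below the RMA value of the same array. That a spreadsheet read decimal numbers as hours and minutes is consistent with the restored values, whose larger median distance over the 2 arrays was 0.0246. Among probe sets with an RMA value of at least 8, a further 33 values on the VLX 50 array and 37 on the DMSO array have fewer digits and are likely altered too. They were picked as over 3 log2 below the level given by RMA and within 1 log2 of it once restored. Probe sets with lower RMA values were not searched. For KDM3A the value of 93.97 reads as 2255.15, which would make it 2.41-fold higher. No biological explanation was tested for this pattern.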
